A study of Mus musculus with 11 samples.

How the data were processed

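Total RNA of mouse hearts was labelled with Cy3 and hybridized to Agilent 8x60K mouse arrays, 1 heart per array, 11 arrays on 2 slides. The hearts of a group came from separate animals per the series design. Per the file headers, the scanned images were quantified with Agilent Feature Extraction 11.5.1.1 under a single-channel protocol on a grid annotated to mm9. Per the file headers, the intensity columns are the processed signal, which the authors' software background-subtracted and detrended without scaling between arrays, and the raw spot and local background pixel medians. Per the file headers, the flag columns, of unit 0 or 1, record spots well above background, saturated spots and spots with uneven or deviant pixels. The deposited value table is in log2 per its values, with column medians of 6.59 to 6.60 and a range of 5.65 to 18.9, made alike between arrays and not centred on 0. limma is named in the submitters' processing notes without a version, and the background method, offset and normalization are not given in the sources used here. With 1 channel, the direction of a ratio does not apply to any column. The deposited table correlated at 0.9999 to 1.000 with spot medians corrected by normexp (offset 50) and quantile normalized here.

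Of 62976 spots, 59305 were not controls and gave 55681 probes after spots of the same probe were averaged by their mean log2 value. Between 95 and 160 spots per array were left out for uneven or deviant pixels, none was saturated, and 52 probes had no remaining spot on some array. The processed signal was taken to log2 and the array's 75th percentile over non-control spots subtracted. Probes well above background on at least 3 of the 11 arrays were kept, and each gene was represented by the probe with the highest mean. Gene symbols came from matching the array's transcript accessions to a RefSeq table (GRCm38.p6) for names only, since the builds differ and no coordinate was used. This named 27656 probes (20972 symbols), and 15881 symbols other than provisional ones were among the 25448 genes tested. Other probes were tested and are called unnamed.

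Before the data were examined, the groups, comparisons, tests, alternatives, gene lists and the rule for named genes were written down. All 11 arrays entered 1 limma model with a mean per group (limma 3.58.1, R 4.3.3, no trend, not robust), and p values were adjusted by Benjamini and Hochberg at 0.05. Gene lists (45 fixed, 852 of their 937 genes measured) were tested with camera of limma at a preset correlation of 0.01 between genes where at least 5 members were measured, which left out the sex-linked and thymocyte lists. A list value is the median log2 difference of its members. A gene's p over its list alone was adjusted over the members only. Two-sided exact permutation tests over all splits of the hearts were used for Tert and for list scores per array. Where a gene was well above background in none of the hearts of 1 group, its fold is called at least. Each of those hearts then takes the larger of its own value and the lowest value well above background on its array, and the fold comes from the difference of the group means. Genes are called separate where every heart of 1 group lies above every heart of the other.

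The genes named are 12 fixed in advance, the 3 lowest by unadjusted p in each direction of each comparison, and the 2 members of each called list with the lowest unadjusted p in its direction, and these examples and the choice among them for the text were made after values were seen. No label pairs hearts by replicate number. Same-numbered MI_empty and control arrays deviated together (correlations of 0.311 to 0.318, 3 pairs), so the numbers were taken to pair these 2 groups on the data alone, a choice made after the calls of both fits were known. Arrays of different numbers were not compared in this way, so a true pairing is not shown. All main values stay unpaired, and the pairing enters only through replicate number as a block. Arrays with markers of other tissues were kept in all main values. Alternatives set in advance were quantile normalization, normexp with quantile normalization, the deposited table, no filter on dim probes, the mean of a gene's probes, trend with robust fitting, slide as a block, arrays of 1 slide only, only the 2 groups compared, replicate number as a block, an estimated correlation between genes, and each array left out in turn. The design had assumed mean spot signal for normexp, and the files hold pixel medians, which were used instead. Alternatives added after seeing the data were array weights and further sets of arrays left out, with and without the slide block.

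The steps were tested on simulated data with 100 changed genes at each of 2 sizes. In the MI_Tert and MI_empty comparison 20 of 100 genes changed 2-fold and 75 of 100 changed 4-fold were recovered with 7 false calls, in MI_empty and control 4 and 50 with 2 false calls, and in MI_Tert and control 8 and 52 with 3. A list shifted by 1 log2 was called in each (adjusted p = 3.8e-28, 4.4e-27 and 6.6e-23), with 1, 1 and 0 of 42 other lists called. The simulated genes varied independently, so these counts do not show how the list test behaves where members of a list vary together. Other splits of the real hearts called up to 30, 30 and 32 lists in these comparisons. Replicates were checked by correlation and principal components, where the first held 49.8% of the variance and set MI_empty 1 (−193) and MI_Tert 2 (−108) apart, and the second, with 16.0%, separated slide 1 (31.1 to 56.3) from slide 2 (−65.6 to −9.49). The overlap of genes changed by infarction with those changed by Tert could not be computed, as no gene was called.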

Results

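Hearts of FVB/N mice aged 1 year were profiled on 11 single-channel Cy3 arrays. MI_empty mice (n = 4) had received adeno-associated virus of serotype 9 with an empty cassette and MI_Tert mice (n = 4) the same vector carrying Tert, the catalytic subunit of telomerase. The left anterior descending coronary artery was then tied off for good, and the hearts of surviving animals were collected 6 weeks later. Control mice (n = 3) had neither vector nor ligation, so virus, surgery and infarction cannot be told apart in comparisons with them. The 4 MI_Tert arrays and control 1 were on slide 1, and the 4 MI_empty arrays with controls 2 and 3 on slide 2. The 75th percentile of the processed signal was 321 to 539 on 10 arrays and 697 on MI_empty 1, and 51.0% to 69.7% of spots lay well above background. The median raw signal of negative control spots was 40 to 43 on the slide 1 arrays and 25.5 to 28.5 on those of slide 2. Replicates correlated at 0.963 to 0.985 among controls, 0.863 to 0.976 in MI_empty and 0.934 to 0.984 in MI_Tert. Levels are log2 signal relative to the array's 75th percentile (mean ± SD), and differences are log2 ± SE from limma unless a fold is named.

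Tert, the gene carried by the vector, was measured by 1 probe. Its level was −1.60 ± 0.44 in MI_Tert (n = 4), −3.87 ± 1.28 in MI_empty (n = 4) and −4.46 ± 2.09 in control hearts (n = 3), and it lay well above background on 4, 3 and 1 of these arrays. All 4 MI_Tert hearts lay above all 4 MI_empty hearts and above all 3 controls (two-sided exact permutation p = 0.0286 for each, the smallest p that 4 against 4 or 4 against 3 allows). In limma Tert was higher in MI_Tert than in MI_empty by 2.28 ± 0.85 (adjusted p = 0.364) and higher than in control by 2.86 ± 0.92. Control 1, which shared the slide of the MI_Tert arrays, had −2.23, and the controls on the other slide −4.76 and −6.38. With slide as a block the Tert difference between MI_Tert and MI_empty was −1.06 ± 1.26, the opposite direction, and that between MI_Tert and control 0.63 ± 0.99. Whether the probe lies inside the transferred sequence was not analysed here.

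**Figure D1:**
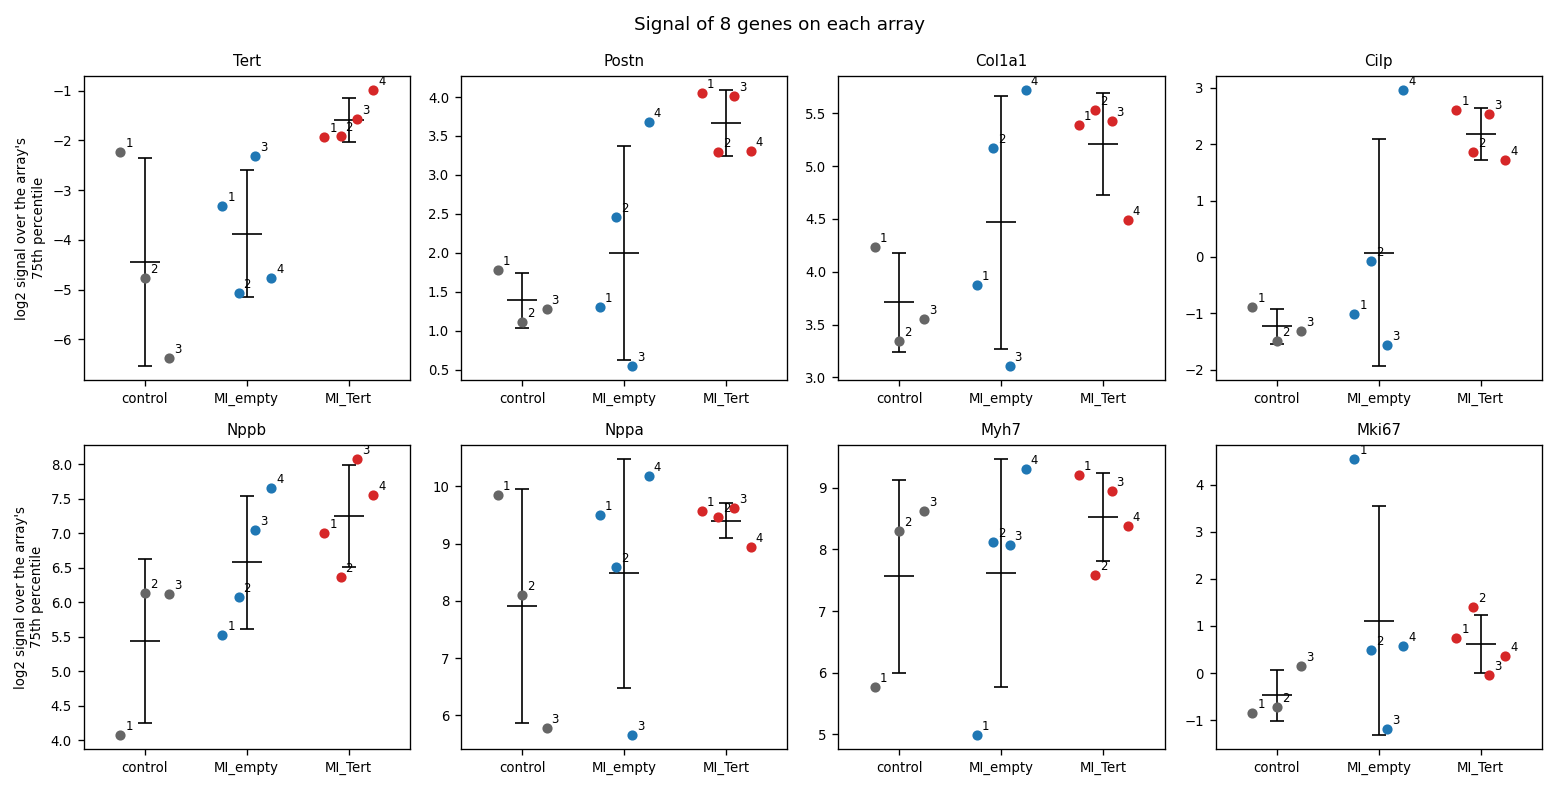
Levels of 8 genes on each array (y axis, log2 over the array's 75th percentile) by group, with each point 1 heart numbered by replicate and bars the mean ± SD. Tert lies at −1.60 in MI_Tert against −3.87 in MI_empty, and Postn at 3.67 in MI_Tert against 1.39 in control.

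Markers of tissues other than ventricle were found on MI_empty 1, MI_empty 4, MI_Tert 2 and MI_Tert 3, and some also on control arrays. MI_empty 1 held Rag1, which cuts antigen receptor genes in developing lymphocytes, at 5.39 against −7.17 to −2.82 on the other 10 arrays, and Dntt, which adds bases at those joints, at 6.81. Foxn1 and Psmb11, made by thymic epithelium, lay well above background on MI_empty 1 alone. Over the thymocyte list (10 genes used, 3 of them well above background on a control array) the median of MI_empty 1 was 7.34 above the control mean, over T cell and NK cell markers 4.30, over mitosis genes 4.44 and over adipocyte markers 4.35. On the same array the sarcomere genes were lower by 3.05 and those of oxidative phosphorylation by 2.25. The thymocyte median was 1.08 on MI_empty 4 and 1.55 on MI_Tert 2. Rag1, at −2.82 on MI_empty 4, and Ptcra, the pre-T cell receptor chain, at −3.98, lay well above background on MI_empty 1 and MI_empty 4 only. MI_Tert 2 had a median of 6.65 over the lung epithelium list (8 genes used, 4 above background on a control array), 3.78 over B cell and 3.74 over adipocyte markers. Its Sftpc, a surfactant protein of the lung alveolus, was at 4.49, and Scgb1a1, secreted by airway club cells, at 8.19 on MI_Tert 2 and 6.16 on MI_empty 1. MI_Tert 3 had a median of 5.52 over skeletal muscle markers (15 genes used, 10 above background on a control array). On it Myh1, a fast skeletal myosin, was at 4.27 and Tnnc2, fast skeletal troponin C, at 6.15, and Myog and Myod1, which switch on skeletal muscle genes, lay above background there alone. Control 2 had Myh1 at −1.60, well above background, and Tnnc2 at 1.57 against −2.22 and −1.77 on controls 1 and 3. Its skeletal muscle median was 0.24. Atrial markers ranged from −1.51 on control 3 to 2.12 on control 1, with Myl7, the atrial myosin light chain, between −2.28 and 7.52 over the arrays.

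**Figure D2:**
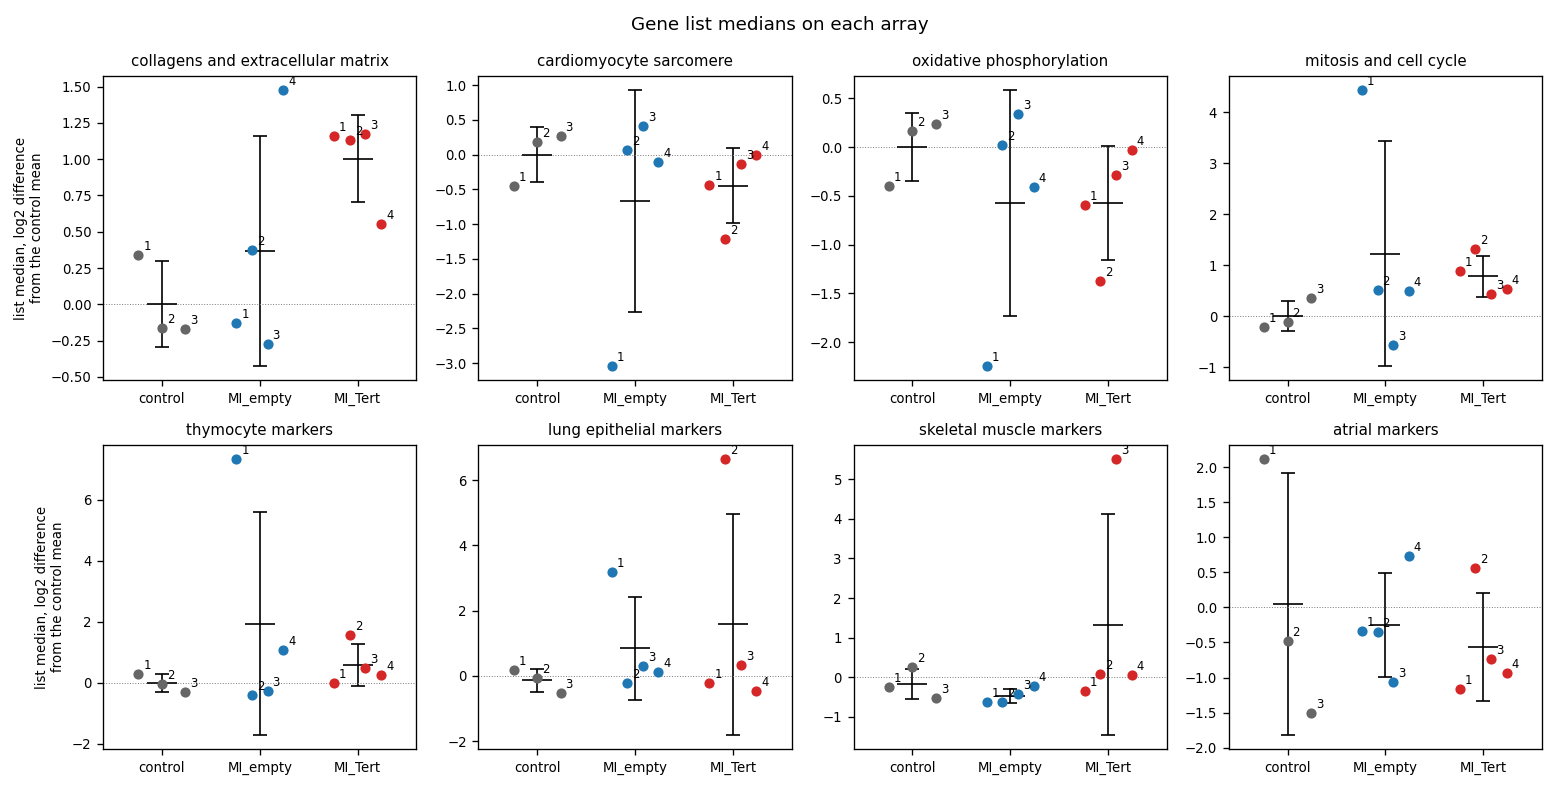
Median over the members of 8 gene lists on each array (y axis, log2 relative to the control mean) by group, with each point 1 heart numbered by replicate and bars the mean ± SD. MI_empty 1 lies at 4.44 for mitosis and −3.05 for the sarcomere list, and MI_Tert 2 at 6.65 for lung epithelium.

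Hearts infarcted under the empty vector were compared with control hearts, and no single gene passed. Ccn2, a matrix-bound growth factor that drives fibrosis, was higher in MI_empty by 1.40 ± 0.57 (n = 4 and 3, and 0.80 without MI_empty 4), and Cthrc1, secreted by activated fibroblasts after injury, by at least 2.72-fold (above background on 3 of 4 MI_empty and 0 of 3 control arrays). Nr4a1, an orphan receptor induced within minutes of a stimulus, was higher by 1.77 ± 0.74 and Btg2, an antiproliferative early gene, by 1.53 ± 0.64. Il1b, an inflammatory cytokine, was higher by 1.101 ± 0.44, and all 4 MI_empty hearts lay above all 3 controls for Il1b, Ccn2 and Cthrc1. limma called 0 of 25448 genes higher and 0 lower at adjusted p under 0.05 (lowest adjusted p = 0.897), with 766 at unadjusted p under 0.05 (219 higher, 547 lower) against 1272 expected by chance. With 1 array left out the unadjusted count ran from 534 (without control 1) to 1466 (without MI_empty 2). Trend with robust fitting, quantile normalization and the authors' own value table also gave 0 genes at adjusted p under 0.05. The count became 1 without control 3 (Olfr791, an odorant receptor, lower), and 4 without MI_empty 2 (Amer3, Tmc3 and 2 unnamed probes, all lower). These genes were chosen after their values were seen.

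Of 43 gene lists tested with a preset correlation, 11 were called higher and 6 lower in MI_empty than in control. All 17 calls were lost with an estimated correlation (adjusted p = 0.803 for each). Collagens and extracellular matrix genes had a median of 0.33 (40 of 50 up, 10 down, adjusted p = 1.4e-05) with array scores of −0.27 to 1.48 in MI_empty. Of its 50 members 4 were higher at unadjusted p under 0.05 and 0 adjusted over the list alone. Col1a1, the main fibrillar collagen of scar, was higher by 0.76 ± 0.57, Col3a1, its partner in young scar, by 0.62 ± 0.49 and Postn, made by activated fibroblasts, by 0.61 ± 0.62, and without MI_empty 4 these were 0.34, 0.29 and 0.05. Chondrocyte and bone markers (0.90, 9 of 11 up, adjusted p = 0.0125) included Acan, a cartilage proteoglycan, at 1.31 ± 0.49. TGF-beta genes (0.23, 15 of 19 up, adjusted p = 0.0134) included Skil, a brake on SMAD signalling, at 0.46 ± 0.25 (0.27 without MI_empty 4). Immediate early genes (0.40, 20 of 22 up, adjusted p = 7.9e-07) and MHC class II genes (1.04, 10 of 10 up, adjusted p = 4.7e-05) were called in every fit that left out 1 array, with medians down to 0.19 without MI_empty 4 and 0.61 without MI_empty 1. Cd74, the chaperone of class II molecules, was higher by 1.18 ± 0.58 and H2-Ab1, a class II beta chain, by 1.13 ± 0.56, and within slide 2 by 0.74 and 0.65. Cytokines (0.29, 20 of 25 up, adjusted p = 0.00154) included Cxcl5, a neutrophil attractant, at least 1.82-fold higher. Macrophage markers (0.14, 17 of 24 up, adjusted p = 0.0386) included Cd14, the endotoxin co-receptor, at 0.41 ± 0.27 (0.18 without MI_empty 4). Stress response genes of the endoplasmic reticulum (0.15, 14 of 22 up, adjusted p = 0.0313) included Sdf2l1, a chaperone partner, at 0.63 ± 0.24. With replicate number as a block the chondrocyte (0.52), TGF-beta (0.15) and endoplasmic reticulum stress (0.13) calls were lost (adjusted p = 0.0916 for each). In none of the 17 lists did a member pass adjusted over the list alone.

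Calls of lists of dividing cells, T cells and heart muscle in MI_empty were lost without MI_empty 1, the array with thymic transcripts. Mitosis genes had a median of 1.23 (35 of 35 up, adjusted p = 1.0e-10) that became 0.12 without MI_empty 1, DNA replication genes 0.65 (31 of 32 up, adjusted p = 1.2e-07) that became 0.05, and T cell and NK cell markers 1.40 (22 of 24 up, adjusted p = 2.1e-06) that became 0.41. The T and NK cell list was called again (0.41, adjusted p = 0.0193) when MI_Tert 2 was left out as well, a set chosen after values were seen. Mki67, a marker of cycling cells, was at 1.11 ± 2.44 in MI_empty against −0.48 ± 0.55 in control, Kif4, a mitotic motor, was higher by 1.95 ± 0.97, and Lck, a T cell kinase, by 2.65 ± 1.74. Without MI_empty 1 Mki67 was higher by 0.44, Kif4 by 0.95 and Lck by 0.85. Oxidative phosphorylation genes had a median of −0.57 (49 of 49 down, adjusted p = 1.2e-05), fatty acid oxidation genes −0.68 (30 of 30 down, adjusted p = 4.1e-05), TCA cycle genes −0.53 (21 of 21 down, adjusted p = 0.00154), ion channels −0.71 (32 of 32 down, adjusted p = 4.1e-05) and sarcomere genes −0.66 (27 of 27 down, adjusted p = 0.00154). Without MI_empty 1 these 5 medians were −0.01, −0.16, −0.01, −0.02 and 0.09, and endothelial markers went from −0.26 (20 of 22 down, adjusted p = 0.0386) to 0.09. Tcap, which caps titin at the Z-disc, was lower by 0.91 ± 0.61, Kcnj2, the inward rectifier channel, by 1.33 ± 0.64, and Acot2, a mitochondrial thioesterase, by 1.08 ± 0.70. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was lower by 0.89 ± 0.74, and Myh6, the adult cardiac myosin, by 0.16 ± 0.37 (its probes −0.77 to −0.16, and 0.18 higher without MI_empty 1). Without MI_empty 1 Tcap was at −0.23, Kcnj2 at −0.71, Acot2 at −0.53 and Atp2a2 at −0.11. Nppb, a peptide released by stretched ventricle, was higher by 1.13 ± 0.66 (0.45 within slide 2), Nppa, its atrial relative, by 0.57 ± 1.098 (−0.49 without control 3) and Cdkn1a, a cell cycle inhibitor, by 0.45 ± 0.65 (−0.04 without MI_empty 4). The genes lowest by unadjusted p were Fgfbp1, a carrier of fibroblast growth factors (−1.24 ± 0.20), Foxd4, a forkhead factor (−1.28 ± 0.21), and Slc26a3, a chloride exchanger (−1.79 ± 0.34).

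With slide as a block, which equals the difference from controls 2 and 3 on slide 2 for MI_empty and from control 1 alone for MI_Tert, 16 of the 17 calls kept their direction and threshold. The block kept MI_empty 1, so it says nothing of the calls that were lost without that array. The medians within slide 2 were 0.49 for extracellular matrix, 0.28 for immediate early genes, 0.69 for MHC class II, 1.16 for mitosis, 0.65 for DNA replication, 1.38 for T and NK cells, −0.77 for oxidative phosphorylation, −0.89 for fatty acid oxidation, −0.91 for sarcomere and −0.82 for ion channels. They were −0.75 for the TCA cycle, 0.48 for cytokines, 0.92 for chondrocyte markers, 0.30 for TGF-beta, 0.37 for macrophages, −0.45 for endothelium and 0.03 for the endoplasmic reticulum stress list, which was no longer called. Leaving out MI_empty 4 took the extracellular matrix median to −0.06, that of chondrocyte markers to −0.24 and that of TGF-beta to 0.04, each no longer called. Without MI_empty 3 these were larger for extracellular matrix (0.59, with Col1a1 at 1.21, Col3a1 at 0.99 and Postn at 1.09) and chondrocyte markers (1.39), as were those of cytokines (0.51), mitosis (1.93), oxidative phosphorylation (−0.87), the TCA cycle (−0.83) and sarcomere (−1.002). The number of lists called was 11 without MI_empty 1, 26 without control 1 and 10 without control 3. Without control 3 the cytokine (0.35), TCA cycle (−0.43), sarcomere (−0.54), chondrocyte (0.87), TGF-beta (0.14), macrophage (−0.05), endothelial (−0.20) and endoplasmic reticulum stress (0.16) lists were not called. Without control 2 the endothelial (−0.25), TGF-beta (0.15) and macrophage (0.05) calls ended. Macrophage markers were also not called without MI_empty 1 (0.14), MI_empty 2 (0.15), MI_empty 4 (0.05) or MI_Tert 1 (0.14), and the endoplasmic reticulum stress list not without MI_empty 3 (0.10), MI_empty 4 (0.13) or control 1 (0.03).

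Hearts infarcted under the Tert vector were compared with the same controls, and again no single gene passed. Cilp, a matrix protein of activated cardiac fibroblasts, was higher in MI_Tert by 3.42 ± 0.88 (n = 4 and 3), Comp, a cartilage matrix protein found in scar, by 4.24 ± 1.36 and Postn by 2.28 ± 0.62, with all 4 MI_Tert hearts above all 3 controls for each. Col1a1 was higher by 1.499 ± 0.57 (5.21 ± 0.48 against 3.71 ± 0.47, hearts separate) and Nppb by 1.81 ± 0.66 (7.25 ± 0.74 against 5.44 ± 1.19, hearts separate, and 1.12 without control 1). Gdf15, a stress cytokine, was higher by 3.45 ± 1.05 and Timp1, an inhibitor of matrix proteases, by 2.95 ± 0.88. limma called 0 of 25448 genes higher and 0 lower (lowest adjusted p = 0.251), with 1843 at unadjusted p under 0.05 (809 higher, 1034 lower) against 1272 expected by chance, and 0 with trend and robust fitting or with quantile normalization. With 1 array left out the unadjusted count ran from 897 (without control 3) to 3640 (without MI_empty 1), on both sides of the number expected by chance. Against control 1 alone, a single heart to which the slide block reduces the controls, 5 passed: St8sia2, which polymerizes sialic acid, at −3.35, Avp, the vasopressin precursor, at −3.57, and 3 unnamed probes, 1 of them higher. The same contrast fitted on the arrays of slide 1 only called 0. Without control 1, 55 genes passed (45 higher, 10 lower), but no control is then left on the slide of MI_Tert, so group and slide cannot be told apart. Without MI_empty 4, 1 passed: Tnmd, a tendon glycoprotein, higher. These genes were chosen after their values were seen.

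Of the 43 lists 19 were called higher and 4 lower in MI_Tert than in control, and the extracellular matrix list had the lowest p. All 23 calls were lost with an estimated correlation (adjusted p = 0.542 to 0.814, and 0.542 for extracellular matrix). The median of that list was 0.94 (48 of 50 up, adjusted p = 1.1e-22), 20 members were higher at unadjusted p under 0.05 and 11 passed adjusted over the list alone. The 4 MI_Tert scores of the list were 0.56 to 1.17 and the control scores −0.17 to 0.34. Mfap5, a microfibril protein, was higher by 1.78 ± 0.53, Ltbp2, which binds fibrillin, by 3.28 ± 0.94 and Col3a1 by 1.13 ± 0.49, and Cthrc1 by at least 3.50-fold (above background on 4 of 4 and 0 of 3 arrays). Chondrocyte and bone markers (1.54, 10 of 11 up, adjusted p = 5.2e-06, 1 adjusted over the list alone), fibroblast markers (0.33, 13 of 20 up, adjusted p = 0.0034) and mesothelial markers (0.59, 10 of 13 up, adjusted p = 0.00472) were also called. Over the alternatives the fibroblast median ran from 0.19 to 0.42 and the mesothelial median from −0.32 to 0.74. Fibin, a secreted fibroblast protein, was higher by 1.67 ± 0.52, Tbx18, an epicardial transcription factor, by 0.66 ± 0.20 and Krt19, a keratin of simple epithelia, by 1.34 ± 0.52. TGF-beta genes had a median of 0.49 (15 of 19 up, adjusted p = 5.2e-06, 6 adjusted over the list alone), with Tgfb2, a ligand of the family, higher by 1.47 ± 0.39 and Ccn2 by 2.08 ± 0.57. Wnt genes (0.43, 20 of 25 up, adjusted p = 0.00582) included Sfrp2, a secreted Wnt modulator, at 4.07 ± 1.36. Natriuretic and fetal genes (0.55, 17 of 22 up, adjusted p = 6.6e-04) included Nppa at 1.49 ± 1.098 (−0.45 within slide 1), Myh7, the slow myosin of the stressed ventricle, at 0.97 ± 0.99 and Acta1, the skeletal actin of the fetal heart, at 1.04 ± 1.48. The members of this list lowest by unadjusted p were Ltbp2 and Timp1, and 7 of its 22 members are also in other lists. Nppa was at 0.43 without control 3 and 2.46 without control 1, Myh7 at 0.07 and Acta1 at 0.12 without control 1, and within slide 1 these last 2 were at 2.76 and 2.87.

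Immune lists were called higher as well. Macrophage markers had a median of 0.43 (22 of 24 up, adjusted p = 1.4e-06, 2 adjusted over the list alone), with Clec4n, a C-type lectin of macrophages, higher by 1.43 ± 0.37 and Cd14 by 1.03 ± 0.27, and a median of 0.22 without control 3. Complement (0.55, 17 of 17 up, adjusted p = 5.2e-06) included C5ar1, the receptor of C5a, at 0.95 ± 0.36, and cytokines (0.64, 20 of 25 up, adjusted p = 3.0e-05) included Ccl9, a monocyte attractant, at 1.44 ± 0.49. Immediate early genes (0.53, 21 of 22 up, adjusted p = 1.8e-06) included Fos, an AP-1 subunit, at 1.58 ± 0.73, and the endoplasmic reticulum stress list (0.29, 17 of 22 up, adjusted p = 1.7e-04) Pdia4, a disulfide isomerase, at 0.91 ± 0.24. Over the alternatives the median of the stress list ran from 0.16 to 0.40 and that of complement from −0.16 to 0.83. Neutrophil markers (1.00, 8 of 12 up, adjusted p = 0.00582) included Lcn2, an iron-scavenging protein, at 1.16 ± 0.38, with a median of 0.52 without MI_Tert 2 and 0.65 without MI_Tert 3. Interferon genes (0.36, 29 of 33 up, adjusted p = 2.1e-04), B cell markers (0.98, 16 of 18 up, adjusted p = 0.00167), MHC class II (0.74, 10 of 10 up, adjusted p = 0.00245) and T and NK cells (0.84, 20 of 24 up, adjusted p = 0.0165) were not called without MI_Tert 2, the array with lung transcripts, where their medians were 0.04, 0.11, 0.14 and 0.05. Interferon genes were called again (0.32) without MI_empty 1, MI_Tert 2 and MI_Tert 3, a set chosen after values were seen. Mitosis genes had a median of 0.83 (34 of 35 up, adjusted p = 1.7e-04) and p53 targets 0.21 (16 of 23 up, adjusted p = 0.036), with Bax, a pore former of apoptosis, higher by 0.38 ± 0.15. Lower in MI_Tert were fatty acid oxidation genes (−0.70, 29 of 30 down, adjusted p = 7.0e-05), oxidative phosphorylation (−0.56, 49 of 49 down, adjusted p = 1.7e-04), ion channels (−0.69, 30 of 32 down, adjusted p = 0.0032) and the TCA cycle (−0.54, 21 of 21 down, adjusted p = 0.00967). Without MI_Tert 2 the medians of fatty acid oxidation, oxidative phosphorylation and ion channels were −0.45, −0.30 and −0.40, that of cytokines 0.39 and that of natriuretic genes 0.97, all still called. Kcnh2, a channel of repolarization, was lower by 1.20 ± 0.40, Kcnj5, an atrial potassium channel, by 1.17 ± 0.43 and Atp2a2 by 0.92 ± 0.74.

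With slide as a block the comparison rests on control 1, a single heart assumed to vary like the other groups, whose atrial markers stood at 2.12. Of the 23 lists 10 were then called in the same direction, with medians of 0.68 for extracellular matrix, 0.81 for immediate early genes, 0.39 for TGF-beta, 0.39 for cytokines, 0.40 for the endoplasmic reticulum stress list, 1.01 for mitosis, 1.01 for natriuretic genes, 1.45 for MHC class II, −0.29 for ion channels and 1.03 for T and NK cells. The other medians within slide 1 were −0.02 for macrophages, −0.16 for complement, −0.32 for mesothelial, −0.10 for Wnt, 0.71 for chondrocyte (called when slide 1 alone was fitted, again against 1 control), 0.03 for interferon, 0.51 for B cell, 0.22 for fibroblast and 0.52 for neutrophil genes. They were −0.22 for fatty acid oxidation, −0.15 for oxidative phosphorylation, −0.13 for the TCA cycle and 0.14 for p53 targets, and Cilp was higher by 3.08 and Nppb by 3.19 within that slide. Nearer 0 there than over all arrays were Comp at 2.23, Sfrp2 at 2.19, Timp1 at 1.63, Col1a1 at 0.97, Col3a1 at 0.50, Krt19 at 0.70, Ccl9 at 0.50 and Atp2a2 at −0.59. Leaving out MI_Tert 2 also ended the Wnt (0.25) and TCA cycle (−0.27) calls. Leaving out control 1 ended those of MHC class II (0.38), T and NK cells (0.51) and p53 targets (0.22), and leaving out control 3 those of Wnt genes (0.32) and p53 targets (0.16). The p53 call was also lost without MI_Tert 1 (0.18) or MI_Tert 3 (0.26), and the extracellular matrix median stayed between 0.90 and 1.13 in all fits that left out 1 array.

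MI_Tert and MI_empty hearts, infarcted under the 2 vectors, were compared across the 2 slides, and no single gene passed. Postn was higher in MI_Tert than in MI_empty by 1.67 ± 0.58 (3.67 ± 0.43 against 2.00 ± 1.37, n = 4 and 4), Col8a1, a short-chain collagen, by 1.54 ± 0.52 and Mfap5 by 1.44 ± 0.49. Krt19 was higher by 1.46 ± 0.48 and Tbx18 by 0.57 ± 0.19, both with all 4 MI_Tert hearts above all 4 MI_empty hearts, and Fibin by 1.53 ± 0.48. In the block of slides Postn was at 1.08, Mfap5 at 0.71 and Krt19 at 0.50. Blm, a helicase of DNA repair, was lower by 1.62 ± 0.29 (−0.44 with slide as a block) and Slco1a4, an organic anion transporter, by 1.48 ± 0.24 (above background on 1 of 4 MI_Tert arrays). Fgfbp1 was higher by 1.12 ± 0.19 and Reg3d, a secreted lectin, by 1.31 ± 0.24 (0.47 with the block). limma called 0 of 25448 genes higher and 0 lower (lowest adjusted p = 0.178), with 2749 at unadjusted p under 0.05 (1577 higher, 1172 lower) against 1272 expected by chance, and 0 with trend and robust fitting, quantile normalization or slide as a block. The unadjusted count was 649 with slide as a block, under the number expected by chance. The block estimates slide from control 1 against controls 2 and 3, which widens the error of this difference. Its count can therefore fall without any slide effect. With 1 array left out the unadjusted count ran from 1952 (without MI_Tert 3) to 3779 (without MI_empty 1). Without the filter on dim probes it was 6835 of 36957 genes, against 1848 expected. A fit of these 2 groups alone called 119 genes (98 higher, 21 lower). The count was 14, all higher, without MI_empty 2, 271 (210 higher, 61 lower) without control 1, 1 without MI_empty 4 (Tnmd, higher by 3.92) and 1 without control 3 (Olfr791, higher by 2.74), and these genes were chosen after their values were seen.

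Of the 43 lists 11 were called higher in MI_Tert than in MI_empty and 1 lower. All 12 calls were lost with an estimated correlation (adjusted p = 0.910 for each). Extracellular matrix genes had a median of 0.65 (48 of 50 up, adjusted p = 6.7e-10, 7 members higher at unadjusted p under 0.05 and 0 adjusted over the list alone), with scores of 0.56 to 1.17 in MI_Tert and −0.27 to 1.48 in MI_empty. Cilp was higher by 2.10 ± 0.81, Col11a1, a fibril-nucleating collagen, by 2.33 ± 1.05, Col1a1 by 0.74 ± 0.53 (−0.05 with slide as a block) and Col3a1 by 0.51 ± 0.45 (−0.44 with the block). Without MI_empty 3 these 2 collagens were at 0.29 and 0.15. Fibroblast (0.43, 17 of 20 up, adjusted p = 0.00957), mesothelial (0.59, 13 of 13 up, adjusted p = 0.00296), chondrocyte (0.79, 9 of 11 up, adjusted p = 0.021) and TGF-beta genes (0.30, 15 of 19 up, adjusted p = 0.0142) were called higher. Tgfb2 was higher by 0.95 ± 0.36 and Tgfbr2, a receptor of the family, by 0.44 ± 0.18 (0.03 with the block). Macrophage markers (0.31, 21 of 24 up, adjusted p = 0.00354) included Cd33, an inhibitory sialic acid receptor, at 0.52 ± 0.19 (0.31 with the block) and Cd14 at 0.62 ± 0.25. Complement (0.43, 17 of 17 up, adjusted p = 0.00664) included Serping1, the C1 inhibitor, at 0.59 ± 0.32 (−0.21 with the block, 0.34 without MI_empty 1), and interferon genes (0.33, 27 of 33 up, adjusted p = 0.00689) Oas2, a sensor of double-stranded RNA, at 0.58 ± 0.29 (−0.25 with the block). Natriuretic and fetal genes (0.61, 19 of 22 up, adjusted p = 0.021) included Timp1 at 2.01 ± 0.82 (0.04 with the block), Nppb at 0.68 ± 0.61, Nppa at 0.92 ± 1.02 (−1.99 with the block) and Myh7 at 0.91 ± 0.92. The block gave 2.74 for Nppb and 3.60 for Myh7. These values rest on control 1, which had Nppb at 4.07 (6.14 and 6.12 on controls 2 and 3) and Myh7 at 5.77 (8.29 and 8.62). Without MI_empty 1 Nppb was at 0.32 and Myh7 at 0.03, and without MI_empty 3 Timp1 was at 1.28 and Nppa at −0.03. Smooth muscle and pericyte markers (0.48, 12 of 13 up, adjusted p = 0.0268) included Cspg4, a pericyte proteoglycan, at 0.71 ± 0.28 (1.19 with the block), and skeletal muscle markers (1.75, 10 of 11 up, adjusted p = 0.0164), which were highest on MI_Tert 3, Myh2, a fast myosin, at 3.80 ± 1.70 (1.72 without MI_Tert 3). DNA replication genes had a median of −0.64 (32 of 32 down, adjusted p = 4.2e-04) and 0.10 without MI_empty 1, the array with thymic transcripts, which scored 2.77 on this list against −0.22 to 0.24 on the other MI_empty arrays. Among them were Pola1, the catalytic subunit of DNA polymerase alpha, lower by 0.66 ± 0.29, and Rfc4, a clamp loader, by 0.53 ± 0.23. These 2 were at −0.41 and −0.34 without MI_empty 1 and at −0.05 and −0.16 with the block. Mki67 was lower by 0.49 ± 0.99 (0.65 higher without MI_empty 1, 0.07 higher with the block). Myh6 was lower by 0.25 ± 0.34 (0.39 higher with the block) and Atp2a2 by 0.03 ± 0.69 (0.47 higher with the block), and Cdkn1a was higher by 0.88 ± 0.60 (0.03 with the block, 0.49 without MI_Tert 3).

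With slide as a block DNA replication (−0.58) and skeletal muscle (2.19) were still called, and extracellular matrix (0.11), TGF-beta (0.08), natriuretic (1.13) and smooth muscle genes (0.60) were not. The medians of 6 lists turned: macrophage −0.42, complement −0.57, mesothelial −0.42, interferon −0.20, fibroblast −0.10 and chondrocyte −0.10. Of these, macrophage and complement genes passed as lower in MI_Tert (camera adjusted p = 0.0121 and 0.00238), the opposite of their calls without the block. Slide is estimated here from control 1 against controls 2 and 3, so these turns rest on 1 heart of slide 1. On all 6 lists control 1 scored above controls 2 and 3. It had 0.67 on complement (against −0.23 and −0.49) and 0.35 on macrophage genes (against −0.04 and −0.37). The block called 17 lists in all. Only the extracellular matrix call was kept in every fit that left out 1 array. Without MI_empty 1 the DNA replication call ended, as did the fibroblast (0.11), natriuretic (0.10), smooth muscle (0.06), TGF-beta (0.30) and skeletal muscle (1.92) calls. Without MI_empty 3 only 4 lists were called. The macrophage (0.22), complement (0.24), interferon (0.14), mesothelial (0.25), fibroblast (0.32), chondrocyte (0.50), natriuretic (0.82), skeletal muscle (1.67), smooth muscle (0.47) and TGF-beta (0.33) lists were not among them. Without MI_empty 4 the number was 20 and interferon (0.24) was not called. Without MI_empty 4 the medians were 1.04 for extracellular matrix, 1.81 for chondrocyte and 0.53 for TGF-beta genes, and Col11a1 was at 3.54, Nppa at 1.48, Myh7 at 1.47, Cdkn1a at 1.37, Col1a1 at 1.16, Nppb at 1.04 and Col3a1 at 0.84. Leaving out MI_Tert 2 ended the macrophage (0.18), complement (0.25), interferon (0.14), smooth muscle (0.31) and chondrocyte (0.88) calls. Leaving out MI_Tert 3 ended those of skeletal muscle (0.18), natriuretic (0.37) and chondrocyte genes (0.60), and leaving out MI_empty 2 those of chondrocyte (0.96), natriuretic (0.63) and TGF-beta genes (0.27).

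**Figure D3:**
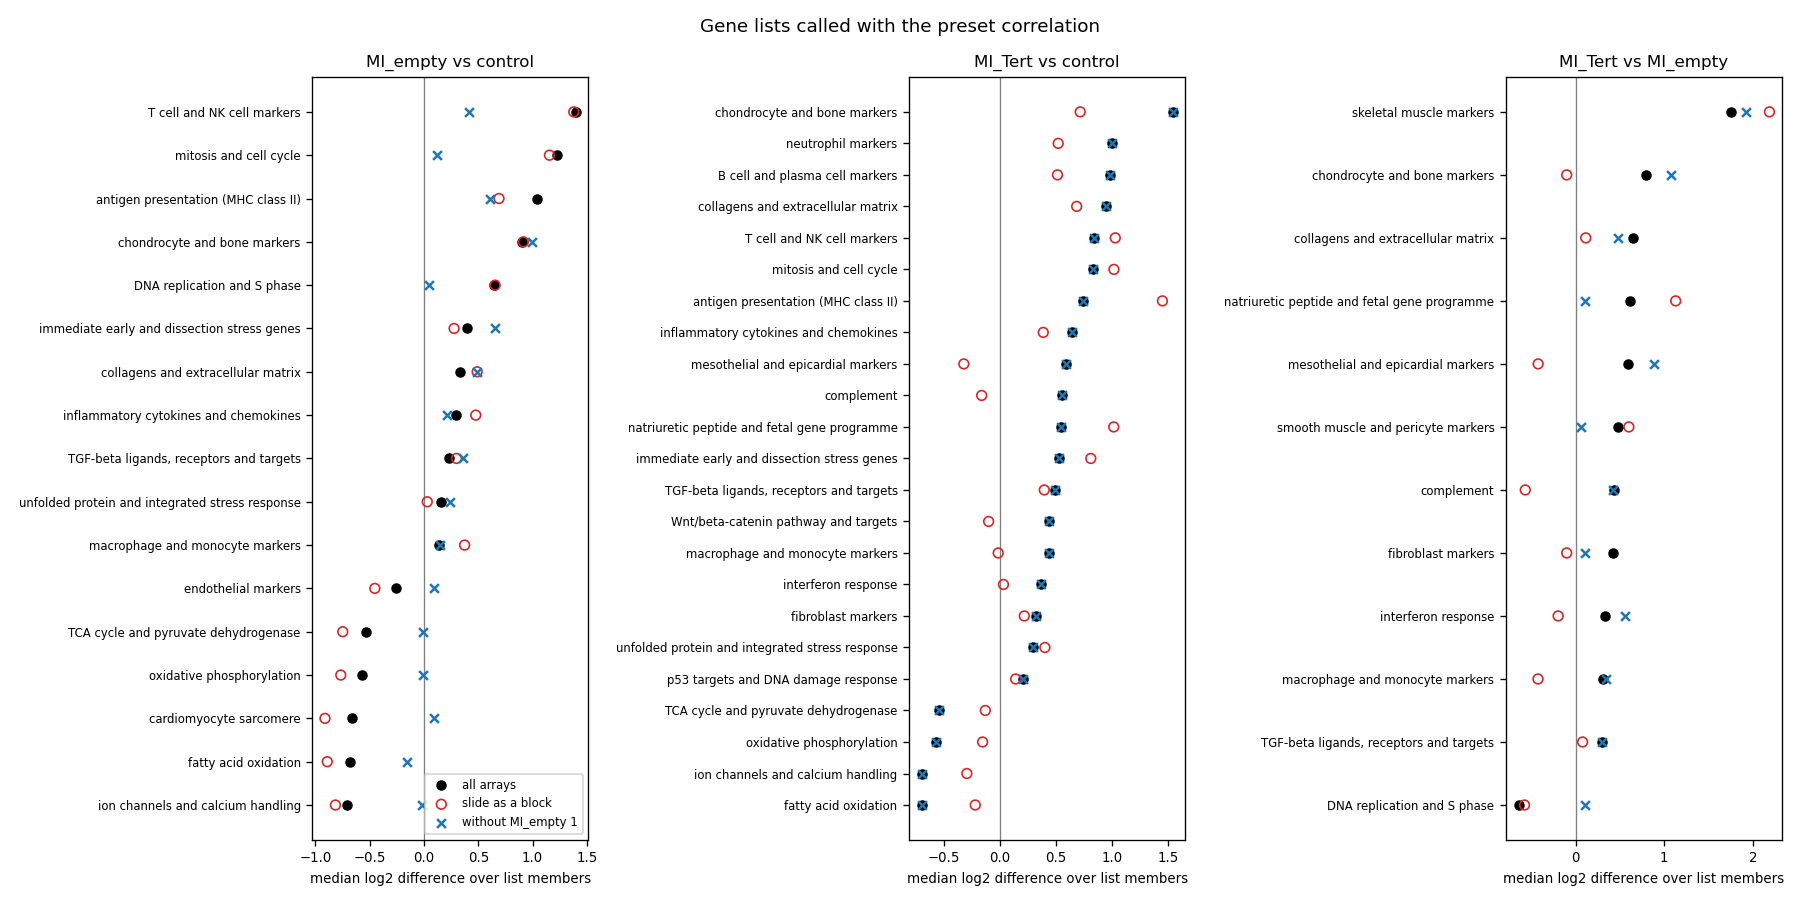
Median log2 difference over the members of each called list (x axis) in the 3 comparisons, with black dots for all 11 arrays, red circles for slide as a block and blue crosses without MI_empty 1. Extracellular matrix in MI_Tert against MI_empty lies at 0.65, 0.11 and 0.48, and DNA replication at −0.64, −0.58 and 0.10.

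Across genes, the change from control to MI_empty was set against the change from MI_empty to MI_Tert with separate MI_empty hearts on the 2 sides. Over 6 ways to place the 4 MI_empty hearts, 2 on each side, the correlation averaged 0.088 (−0.13 to 0.43) and the covariance 0.063 (−0.045 to 0.292), and the highest value came with MI_empty 1 and MI_empty 4 on the side of the infarct change. With all 4 MI_empty hearts on both sides the correlation was −0.42 and the covariance −0.128. The changes of MI_empty and MI_Tert against the same 3 controls correlated at 0.509 (covariance 0.161). In 100 data sets drawn without any change the shared controls alone gave 0.573 (0.554 to 0.598) and a covariance of 0.146 (0.136 to 0.156). The drawn genes varied independently, so these ranges leave out variation that real genes share. The observed 0.509 and 0.161 therefore cannot be judged against the ranges. Genes are not independent replicates, and the 3 controls cannot be divided with 2 hearts on each side.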

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

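The tests of mature T cells in MI_empty 1, of other tissue in MI_empty 1, of slide in the extracellular matrix list and of MI_empty 3 alone were chosen after the result was seen, and the other tests before. Of 118 values tested within groups of 4, 17 had a heart far from the others, where 5.9 are expected by chance, and 9 of the 17 lay in MI_empty 1.

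MI_empty 1 stood apart from the other 3 MI_empty hearts in its sarcomere list (−3.05 relative to the control mean), DNA replication (2.77), T and NK cells (4.30), lung epithelium (3.20), endothelium (−1.51), angiogenesis (−0.99) and brown fat lists (1.00), in Acta1 (1.48 against 6.94 to 7.91) and in the 75th percentile of its signal (697 against 327 to 371). Its thymocyte list, outside the tested lists, lay at 7.34 with controls at −0.31 to 0.29, that of MI_Tert 2 at 1.55 and that of MI_empty 4 at 1.08. A second list of thymocyte genes lay 5.10 above the mean of the other 10 arrays on MI_empty 1, which is what thymus RNA in the sample would give. On this second list MI_Tert 2 scored 0.0027 and MI_empty 4 0.24 relative to the control mean, with MI_empty 2 at 0.26, so it did not set those 2 arrays apart. Mature T cells in the infarct would not carry the recombination genes Rag1, Rag2, Dntt and Ptcra, which lay 8.59 above the other arrays while a second list of mature T cell genes lay 1.66 above. Rag1, Rag2 and Ptcra were well above background on 2 arrays each, so the size of the first difference rests largely on background values. Array brightness and scaling would leave the authors' normalized values level, yet there the sarcomere probes of MI_empty 1 were lower by 2.01 (2.54 in the scaling used here).

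The 2749 genes at unadjusted p under 0.05 between MI_Tert and MI_empty may carry the slide, since the groups share none. With slide as a block the count was 649. The block also widens the error of this difference, so this fall alone does not show a slide effect. The difference of control 1 on slide 1 from controls 2 and 3 on slide 2 correlated with that of MI_Tert from MI_empty at 0.371 across genes, as slide would give, although a single control heart on slide 1 also brings its own atrial content. If other tissue in MI_empty 1 were the whole cause, few of these genes would keep direction and unadjusted p under 0.05 without that array. Of them 2034 did, against 1932 to 2172 without 1 of the other MI_empty arrays. These genes were picked with MI_empty 1 in the fit, where 1 far heart widens a gene's spread. Genes driven by that heart alone would seldom be among them, so this test cannot exclude other tissue there. Without that array the unadjusted count was 3779. No slide holds both vectors, so Tert and slide are told apart only through the controls, 1 of them on slide 1, and no biological explanation was tested.

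The extracellular matrix list, higher in MI_Tert than in MI_empty by 0.65, was weighed against slide and single arrays. With slide as a block its median was 0.11 (adjusted p = 0.351, over all its alternatives 8.9e-26 to 0.910), which leaves slide and vector undecided. Other tissue in MI_empty 1 would take the difference away, and without that array it was 0.48 (adjusted p = 7.6e-06). MI_empty 3 alone would do the same, and without it the median was 0.48 (adjusted p = 1.4e-04). These 2 arrays had the lowest scores of their group (−0.13 on MI_empty 1 and −0.27 on MI_empty 3). Each fit kept 1 of them and none left out both. The median stayed above 0 without either, but these adjusted p rest on the preset correlation. With it 34 of 35 splits of the hearts gave as many lists. Over all hearts the scores were −0.27 to 1.48 in MI_empty against 0.56 to 1.17 in MI_Tert (exact permutation p = 0.229). Neither array alone nor the 2 together are therefore excluded. MI_empty 4 had the highest score of its group (1.48), and infarct size was not measured on the arrays.

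Whether a chance split of the hearts gives as much was counted over 35 splits for each comparison, taken without regard to replicate number. Between MI_Tert and MI_empty 7 of the 35 splits gave as many genes at unadjusted p under 0.05 (2749, highest other 7467) and 34 as many lists (12, highest other 30). Between MI_empty and control 21 gave as many genes (766, highest other 6584) and 31 as many lists (17, highest other 30), and between MI_Tert and control 3 as many genes (1843, highest other 2637) and 12 as many lists (23, highest other 32). Chance is not excluded for any of these 6 counts. The split with 7467 genes put MI_empty 1 and MI_Tert 2 on the same side, so the arrays with other tissue also shape these counts.

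MI_Tert 2 stood apart in its group in lung epithelium (6.65), T and NK cells (2.91), MHC class II (2.23) and nerve and Schwann cell markers (0.91). MI_Tert 3 stood apart in skeletal muscle markers (5.52). MI_Tert 4 stood apart in extracellular matrix (0.56) and Col1a1 (4.49 against 5.39 to 5.53). MI_empty 4 stood apart in nerve and Schwann cell markers (0.22).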

How the results depend on the processing

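No named gene passed with all arrays. Over 155 named gene and comparison values, 3686 results under alternatives kept direction and stayed uncalled, 67 kept direction and passed, and 54 turned. Tert between MI_Tert and MI_empty was 1.88 to 2.80 with 1 array left out. The spots well above background (51.0% to 69.7% per array) limit what dim genes show. Among dim, middle and bright genes 17.8%, 9.89% and 4.75% had unadjusted p under 0.05 between MI_Tert and MI_empty. Negative control spots had a higher median raw signal on slide 1 (40 to 43) than on slide 2 (25.5 to 28.5). Background thus differed between the slides of these 2 groups, and its part in the differences of dim genes was not tested. Where no cause is named below, the cause was not tested.

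Genes called between MI_Tert and MI_empty (0 with all arrays) were 119 with only the 2 groups compared, where the spread no longer includes control, and 0 to 271 with 1 array left out. Among alternatives chosen after seeing the data they were 986 with array weights, 390 without MI_empty 1, MI_Tert 2 and control 1, 54 without these and MI_Tert 3, and 1, an unnamed probe, with the slide block and without MI_empty 1. Array weights ran from 0.08 (MI_empty 1) to 5.14 (control 2). Control 1, the only control on slide 1, had 0.37, and fits without it set MI_Tert on slide 1 against controls on slide 2 only. Between MI_empty and control the count was 0 to 4 with 1 array left out, and the same unnamed probe made it 1 with array weights, with the slide block without MI_empty 1, without MI_empty 1 and MI_Tert 2 or without these and MI_Tert 3, and, with no block, without MI_empty 1, MI_Tert 2 and control 1 or without these and MI_Tert 3. Between MI_Tert and control it was 5 with slide as a block, 1 with only the 2 groups compared (Tnmd), 0 to 55 with 1 array left out, 5670 with array weights, 263 without MI_empty 1, MI_Tert 2 and control 1 and 6 without these and MI_Tert 3. With the slide block it was 12 without MI_empty 1, 1 without MI_Tert 2 (Cfap157, chosen after values were seen), 38 without both and 3 without both and MI_Tert 3.

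Lists called between MI_Tert and MI_empty (12 with all arrays) were 19 with normexp and quantile normalization, 4 without a filter on dim probes (1 higher and 3 lower), 0 with an estimated correlation, and 4 to 20 with 1 array left out. They were 19 with the slide block without MI_Tert 2 and 7 in each of the 4 sets without MI_empty 1 and MI_Tert 2, alone or with MI_Tert 3, control 1 or both. Between MI_empty and control (17) they were 26 with slide as a block, 29 with arrays of 1 slide only, 0 with an estimated correlation, 10 to 26 with 1 array left out, and with the slide block 27 without MI_Tert 2 and 29 without MI_empty 3. Between MI_Tert and control (23) they were 12 with slide as a block, 13 with arrays of 1 slide only, 0 with an estimated correlation, 19 to 29 with 1 array left out, and with the slide block 12 without MI_empty 1, 12 without MI_empty 1 and MI_Tert 2, 10 without MI_Tert 2, 10 without both and MI_Tert 3, and 13 without MI_empty 3.

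With slide as a block the medians of 6 lists turned between MI_Tert and MI_empty (chondrocyte −0.10, complement −0.57, fibroblast −0.10, interferon −0.20, macrophage −0.42, mesothelial −0.42). Complement and macrophage genes passed as lower there, with slide estimated from control 1 against controls 2 and 3 only. The block and the arrays of 1 slide turned 3 between MI_Tert and control (Wnt −0.10, complement −0.16, mesothelial −0.32), where control 1 alone is left to compare with and is assumed to vary like the other groups. Between MI_empty and control the sarcomere and endothelial medians were 0.0884 and 0.0901 without MI_empty 1 and MI_Tert 2, and again 0.0884 and 0.0901 without MI_Tert 3 as well, and the endothelial median was 0.0179 with array weights. Between MI_Tert and MI_empty the smooth muscle median was −0.0440 without MI_empty 1 and MI_Tert 2 and −0.0539 without MI_Tert 3 as well. With 1 array left out DNA replication between MI_Tert and MI_empty ran from −0.89 to 0.10, and between MI_empty and control sarcomere ran from −1.002 to 0.0884, endothelium from −0.453 to 0.0901, oxidative phosphorylation from −0.872 to −0.00850 and macrophages from −0.0521 to 0.374. The correlation across genes of the infarct change and the Tert change was −0.42 with all MI_empty arrays on both sides, where a shared mean with opposite signs lowers it.

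Among named genes, slide as a block turned between MI_Tert and MI_empty Tert (−1.06), Nppa (−1.99), Myh6 (0.390), Atp2a2 (0.466), Col1a1 (−0.0476), Col3a1 (−0.439), Mki67 (0.0719), Serping1 (−0.212), Oas2 (−0.246) and Oasl1 (−0.586). The block and the arrays of 1 slide turned Myh7 between MI_empty and control (−0.838), and Nppa (−0.450) and Myh6 (0.0161) between MI_Tert and control. Atp2a2 between the vectors was 0.130 with quantile normalization, 0.241 with normexp and 0.283 in the authors' table, where Myh6 was 0.00365. Myh6 was 0.0321, 0.0514 and 0.0209 under the same 3 between MI_empty and control, and 0.0271 with normexp and 0.0245 in the authors' table between MI_Tert and control. Mki67 between the vectors was 0.393 without MI_empty 1 and MI_Tert 2, 0.594 without MI_Tert 3 as well and 0.0406 with array weights. In those 3 settings Myh6 between MI_empty and control was 0.177, 0.177 and 0.0258 and Acta1 1.14, 1.14 and 0.0793.

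With 1 array left out, between the vectors Acta1 ran from −0.104 to 2.06, Mki67 from −1.26 to 0.654, Atp2a2 from −0.809 to 0.372 and Nppa from −0.0288 to 1.48. Between MI_empty and control Myh6 ran from −0.374 to 0.177, Acta1 from −1.23 to 1.14, Myh7 from −0.838 to 0.939, Cdkn1a from −0.0448 to 0.730, Tert from −0.381 to 1.69 and Nppa from −0.491 to 1.54.

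Deviations of same-numbered arrays correlated at −0.43 to 0.44 between MI_empty and MI_Tert and at −0.19 to 0.15 between MI_Tert and control. With no common sign, no pairing was assumed for these hearts, although the block by replicate number also held the MI_Tert arrays. With replicate number as a block 0 genes were called in each comparison, and 13 lists between the vectors, 18 between MI_empty and control and 27 between MI_Tert and control. Under that block Myh7 between MI_empty and control was −0.198, and the chondrocyte, TGF-beta and endoplasmic reticulum stress calls of the 17 were lost there, and the other 14 were kept. The median of all genes moved to 0.105 between MI_Tert and MI_empty with the slide block without MI_Tert 2, to −0.113 between MI_empty and control with the block without MI_empty 3, and to −0.104 between MI_Tert and control without control 1.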

Other observations

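Telomere maintenance genes, which act where Tert does, had a median of −0.15 (mean −0.03, adjusted p = 0.165) between MI_Tert and MI_empty, 0.15 between MI_empty and control and −0.16 (mean 0.09, adjusted p = 0.84) between MI_Tert and control. Angiogenesis genes had 0.09, −0.16 and 0.03 (mean −0.02) in the same comparisons. Between the vectors glycolysis genes had 0.10, antioxidant genes 0.17 and circadian genes 0.21, and none of these lists was called. MI_empty 1 scored 0.52 on telomere maintenance genes, against −0.08 to 0.10 on the other MI_empty arrays and −0.17 to −0.02 in MI_Tert. It was the lowest MI_empty array on angiogenesis (−0.99), glycolysis (−1.37), antioxidant (−0.87) and circadian genes (−0.97). Mitosis genes were lower in MI_Tert than in MI_empty by 0.44 with all arrays (adjusted p = 0.126, and 0.972 with an estimated correlation) and higher by 0.63 without MI_empty 1, the array with thymic transcripts. Sarcomere genes had a median of 0.19 between the vectors and −0.60 without MI_empty 1, and oxidative phosphorylation genes −0.03 and −0.57. These fits kept MI_Tert 2, the array with lung transcripts, which scored 1.32 on mitosis, −1.21 on sarcomere and −1.37 on oxidative phosphorylation genes. The other MI_Tert arrays scored 0.43 to 0.88, −0.44 to −0.0041 and −0.60 to −0.03. p53 targets had a median of 0.05 between the vectors and were not called. Their scores per array were 0.19 to 0.25 in MI_Tert against −0.13 to 0.12 in MI_empty and −0.01 to 0.03 in control, with the 4 MI_Tert hearts above all others (two-sided exact permutation p = 0.0286 for each, the smallest possible, and 0.686 and 0.457 adjusted over all lists). TGF-beta genes were likewise separate between MI_Tert (0.39 to 0.61) and control (−0.10 to 0.21). Endothelial markers were higher in MI_Tert by 0.21 (adjusted p = 0.0915) and lower by 0.17 without MI_empty 1, which scored −1.51 against 0.03 to 0.12 on the other MI_empty arrays. MI_Tert 2, kept in both fits, scored −0.44 on them against −0.14 to 0.06 on the other MI_Tert arrays.

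Atrial markers had a median of −0.51 between MI_Tert and MI_empty (adjusted p = 0.65) and −2.57 with slide as a block, and platelet markers −0.12 and −2.70. Control 1, the lone control on slide 1, lay 2.12 above the control mean in atrial markers. Over the arrays Sln, a regulator of the atrial calcium pump, ran from −3.42 to 8.69 and Myl4, an atrial and fetal light chain, from 1.01 to 9.41. Adipoq, secreted by fat cells, ran from −4.71 to 4.81, and the adipocyte list from −2.24 on control 3 to 4.35 on MI_empty 1. Ddx3y, a Y-linked gene, lay at 1.77 to 2.45 on all 11 arrays, and Xist, expressed from the inactive X, was above background on 0 of 11. Exact permutation of list scores per array called no list in any comparison (lowest adjusted p = 0.686 between the vectors, 0.884 for MI_empty and 0.457 for MI_Tert against control). With a smallest exact p of 0.0286 and 48 lists a single fully separated list cannot pass that adjustment. The extracellular matrix scores were 0.36 ± 0.79 in MI_empty, 1.00 ± 0.30 in MI_Tert and 0.00 ± 0.29 in control (exact permutation p = 0.229 between the vectors and 0.0571 between MI_Tert and control).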
